A study of Mus musculus with 3 samples.

How the data were processed

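Polyadenylated RNA of wild-type mouse embryos at E13.5 was read from 3 segments of the gut, the presumptive ileum, the caecum and the colon, with 1 sample per segment. Per the labels, the small intestine was divided into 3 equal portions and the last was taken as the ileum, RNA was extracted with RNeasy from tissue kept in RNAlater, and TruSeq libraries were sequenced as paired 100 bp reads. The submitters' processing notes name Bowtie 0.12.7, DESeq and the mm9 genome, without stating the role of each step.

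The deposited table holds 33762 Ensembl features with 2 kinds of value. Per the file headers, one kind is expected counts, which the authors gave with fractions of 0.5 in places, and the other is RPKM, scaled by the authors to gene length and library depth. The program that counted the reads, the annotation release and the use of strand were not given in the labels or headers, so overlapping genes on opposite strands were not told apart here. Each segment has 2 columns of each kind, which the headers label as replicates 1 and 2 and which come from 1 sample. The mean squared difference between the 2 count columns was 0.422, 0.449 and 0.438 times the counting variance in the ileum, caecum and colon, and 67.5, 52.3 and 46.2 times between caecum and ileum, caecum and colon, and colon and ileum. The columns also held these fractions in the same genes, at 100.0% of genes. They were therefore read as 1 library, averaged, and the mean was rounded to whole counts. RPKM values are the authors' and were averaged over both columns. Whether the replicates are sequencing runs, libraries or something else was not stated.

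The mean totals were 50079617, 64439701 and 50772855 counts in the ileum, caecum and colon, with 22484, 23080 and 23000 features counted at all and 17041, 17658 and 17205 at 20 counts or more. Mitochondrial transcripts took 2.84%, 2.67% and 2.62% of counts, and the 50 most abundant features 11.1%, 10.7% and 10.9%. Libraries were scaled by TMM with edgeR 4.0.16 in R 4.3.3. Folds are ratios of scaled counts, with exact Clopper-Pearson 95% intervals of the conditional binomial, which cover counting error only. A gene entered a comparison with at least 20 counts in the higher library and was counted as apart at a fold of 2 or more. Where the lower library had 0 counts, the fold was computed against a floor of 3 counts and is given as at least that value. This floor is the one-sided 95% upper limit of a count of 0, so these values lie above the lower end of a two-sided interval. No test across samples was possible with 1 library per group, so no p-value is given.

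The procedure was tested on simulated libraries. In 20 sets of libraries that differed by counting noise only, the numbers of genes 2-fold or more apart were taken as the noise values in the report. In a further set with 200 genes altered by known folds, 0.245%, 0.267% and 0.266% of unaltered genes came out 2-fold or more apart for caecum and ileum, caecum and colon, and colon and ileum. All genes altered by 4-fold and 8-fold were recovered, and of those altered by exactly 2-fold 54.0%, 58.0% and 56.0% were. Intervals covered the true fold of unaltered genes in 95.3%, 95.4% and 95.3% of cases. For altered genes, in sets of 50 per fold, coverage ran from 90.0% to 100%. The simulated counts held counting error only, as the intervals assume.

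The comparisons, the scaling, the 33 gene lists, the naming rule and most alternatives were fixed before the data were examined. Named for each pair of tissues were the 12 genes with the highest and the 12 with the lowest bound nearest to no difference, leaving out predicted genes, clone and Riken identifiers and ribosomal, histone and mitochondrial genes. For the caecum against both neighbours, the 10 genes with the largest smaller bound were named in each direction. All members of the HoxD list were named, and of every other list 2 to 4 members with large bounds and some within 2-fold. Some genes that these rules select are not reported here. Features between Atp5g3 and Hnrnpa3 were read as the HoxD region. The lists cover the 4 Hox clusters, regional transcription factors, caecal budding, 5 signalling pathways, cell types of the gut, neighbouring organs, and proliferation, stress, matrix, sex-linked and housekeeping genes. They hold 463 entries for 444 genes, of which 455 were matched by symbol and 5 by identifier, and Prac1, Ahsp and Bapx1 were not matched. List medians use members with at least 20 counts in the higher library, with counts of 0 set to the floor, and were placed among 10000 random lists of the same size, matched on expression in 10 steps. Lists of yolk sac, basal keratinocyte, urothelium, urea cycle, pericyte, guidance and GDNF or endothelin genes were added after values were seen.

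Coordinates are those of the table in mm9, with starts counted from 1. The GENCODE vM21 annotation, built on another assembly, served only for current names and gene types by identifier, which it gave for 29558 features. Some features are overlapping or near-identical, such as Hba-a1 and Hba-a2, Hbb-b1 and Hbb-b2, the Sprr2a copies, the 2 Cbln1 identifiers, and Xist with Tsix. These are not independent genes, but they were not merged. Each therefore counted as its own feature in the numbers of genes and in the lists that hold it. Alternatives were median-of-ratios factors from DESeq2 1.42.0, total counts, upper quartile, total counts without haemoglobin, mitochondrial and the 50 most abundant features, no count minimum, a minimum of 100 counts, intervals wholly beyond 2-fold, a fold of 4, and each count column alone. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Raw reads, splice forms and unannotated transcripts of the HoxD region were not analysed here.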

Results

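The HoxD cluster had a different profile of transcripts in each of the 3 segments of the E13.5 mouse gut. Hoxd9, Hoxd10 and Hoxd11, homeobox genes from the middle of the cluster, were most abundant in the caecum library, at 24.3, 24.1 and 22.7 RPKM, and nearly absent from the ileum library, at 12, 2 and 2 counts. They were 219-fold (125 to 425), 1583-fold (438 to 13073) and 3051-fold (844 to 25198) higher in the caecum than in the ileum, where brackets give 95% intervals. Against the colon they were 11.6-fold (10.1 to 13.3), 5.01-fold (4.61 to 5.45) and 2.53-fold (2.42 to 2.65) higher in the caecum. Hoxd13, the gene at the 5' end of the cluster, was counted almost only in the colon, with 1, 13 and 2354 counts in the ileum, caecum and colon, and was 229-fold (134 to 431) higher there than in the caecum. Hoxd12, its neighbour, had 0, 171 and 882 counts and was 6.52-fold (5.53 to 7.73) higher in the colon than in the caecum. Evx2, a homeobox gene beside Hoxd13, had 384 counts in the colon and 0 in the other libraries, which put the colon at least 162-fold higher than the caecum.

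Hoxd8, Hoxd4 and Hoxd3, toward the 3' end of the cluster, were present in all 3 segments and again highest in the caecum library. In that order they were 2.15-fold (1.99 to 2.33), 2.63-fold (2.45 to 2.83) and 2.27-fold (2.19 to 2.36) higher in the caecum than in the ileum, and 2.99-fold (2.73 to 3.27), 4.54-fold (4.15 to 4.97) and 4.24-fold (4.04 to 4.45) higher than in the colon. The same 3 genes were slightly higher in the ileum than in the colon, by 1.39-fold (1.25 to 1.54), 1.73-fold (1.55 to 1.92) and 1.87-fold (1.77 to 1.97). Hoxd1, the gene at the 3' end, was sparse, with 12, 78 and 2 counts, and was 5.0-fold (2.70 to 10.1) higher in the caecum than in the ileum. In all, 7 of the 9 Hoxd genes were at least 2-fold higher in the caecum than in both other libraries. Gm14396 and 1700109F18Rik, other transcripts of the cluster, were also highest in the caecum library. Gm14396, which lies between Hoxd10 and Hoxd9, had 0, 493 and 40 counts. 1700109F18Rik, now named Hoxd3os1, had 55, 518 and 74, but it overlaps Hoxd8 and Hoxd3, and its reads were not told apart from theirs. The genes that flank the cluster differed little, since Lnp, Mtx2, Atp5g3 and Hnrnpa3 stayed within 2-fold in every comparison. Lnp had 7.44, 6.33 and 8.23 RPKM and Mtx2 18.9, 17.9 and 16.0 RPKM in the ileum, caecum and colon.

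The region read here spans 73746504 to 75507464 on chromosome 2 of mm9 and holds 28 features, of which 19 had at least 20 counts in a library. All Hoxd genes lie on the plus strand, from Hoxd13 (ENSMUSG00000001819, chromosome 2, 74506367 to 74509656) to Hoxd1 (ENSMUSG00000042448, chromosome 2, 74601037 to 74603200). Between them lie Hoxd12 (chromosome 2, 74512986 to 74515763), Hoxd11 (ENSMUSG00000042499, chromosome 2, 74517449 to 74525798), Hoxd10 (chromosome 2, 74529147 to 74533163), Gm14396 (chromosome 2, 74533577 to 74535432), Hoxd9 (chromosome 2, 74535737 to 74538265), Hoxd8 (chromosome 2, 74542672 to 74545990), Hoxd3 (chromosome 2, 74549986 to 74586331) and Hoxd4 (chromosome 2, 74560035 to 74567217). Evx2 lies at chromosome 2, 74491049 to 74497918. The span of Hoxd3 contains Hoxd4, and 1700109F18Rik overlaps Hoxd3 and Hoxd8 on the other strand, so reads of these genes were not told apart here. Each tissue had 1 sample, whose 2 columns the file headers label as replicates. The columns differed by less than counting error and were read as 1 library, so no difference in this report has a replicate check, and every interval covers counting error only.

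**Figure D1:**
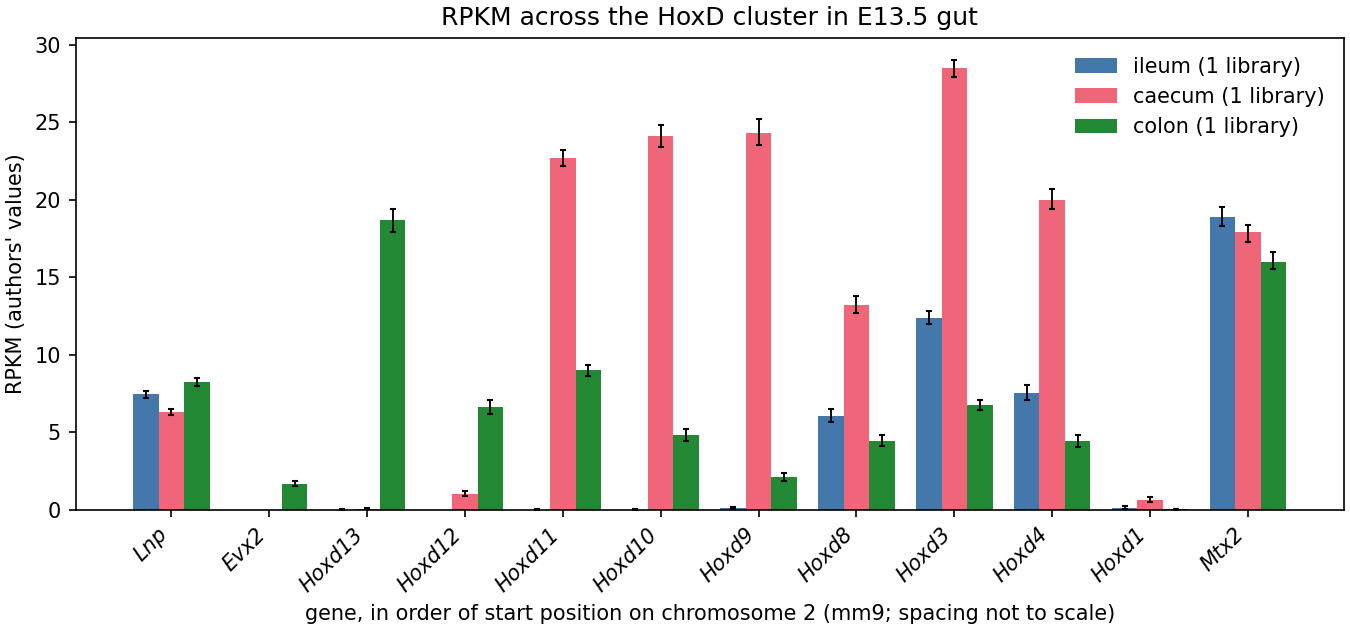
RPKM of the Hoxd genes, Evx2 and the flanking genes Lnp and Mtx2 in the order of their start on chromosome 2 (mm9), with 1 bar per library (ileum, caecum, colon) and error bars that give the 95% Poisson interval of the count. The caecum bar is tallest from Hoxd11 to Hoxd1, and the colon bar from Evx2 to Hoxd12.

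The HoxA and HoxC clusters showed the same contrast, with genes of groups 10 and 11 nearly silent in the ileum and higher in the caecum and colon. Hoxc11 was sparse in the colon, with 0, 204 and 38 counts in the ileum, caecum and colon. Hoxa10 had 4, 14018 and 5872 counts in the ileum, caecum and colon. Hoxa11 had 0, 3078 and 1886, while Hoxa9 had 143, 3800 and 1516. Hoxa10 was 2694-fold (1052 to 9890) higher in the caecum than in the ileum and 1.89-fold (1.83 to 1.95) higher than in the colon. Hoxc10 was 275-fold (107 to 1010) higher in the caecum than in the ileum and 6.08-fold (5.22 to 7.12) higher than in the colon, and Hoxb9 was 4.54-fold (3.71 to 5.61) higher than in the ileum. Group 13 genes other than Hoxc13 marked the colon. Hoxa13 was 36.0-fold (28.9 to 45.6) higher there than in the caecum, Hoxb13 had 620 counts in the colon and 0 elsewhere, and Hoxc13 and Hoxc12 had 0 counts in all 3 libraries. Evx1, the partner of Evx2 at the HoxA cluster, was 34.1-fold (13 to 128) higher in the colon than in the caecum.

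HoxB and HoxC genes of groups 4 to 8 ran the other way and were highest in the ileum library. Hoxc8 was 16.0-fold (14 to 18.4) higher in the ileum than in the caecum and 68.1-fold (50.2 to 94.6) higher than in the colon. Hoxc4, Hoxc5 and Hoxc6 were 23.8-fold (17.9 to 32.3), 18.4-fold (13.6 to 25.5) and 18.5-fold (14.8 to 23.4) higher in the ileum than in the colon, with the caecum in between. Hoxb8 followed the same order, with 1449, 508 and 142 counts, as did Hoxb7 and Hoxb6. Hoxb3 and Hoxa3 stayed within 2-fold in every comparison. The list medians, given in log2 for caecum over ileum, caecum over colon and colon over ileum, were 1.29, 0.75 and 0.12 for HoxD with its flanking genes, 0.16, 0.58 and -0.41 for HoxA, -1.02, 0.13 and -0.50 for HoxB and -1.83, 2.09 and -4.20 for HoxC. With a minimum of 100 counts the HoxD median for caecum over colon fell from 0.75 to 0.16.

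**Figure D2:**
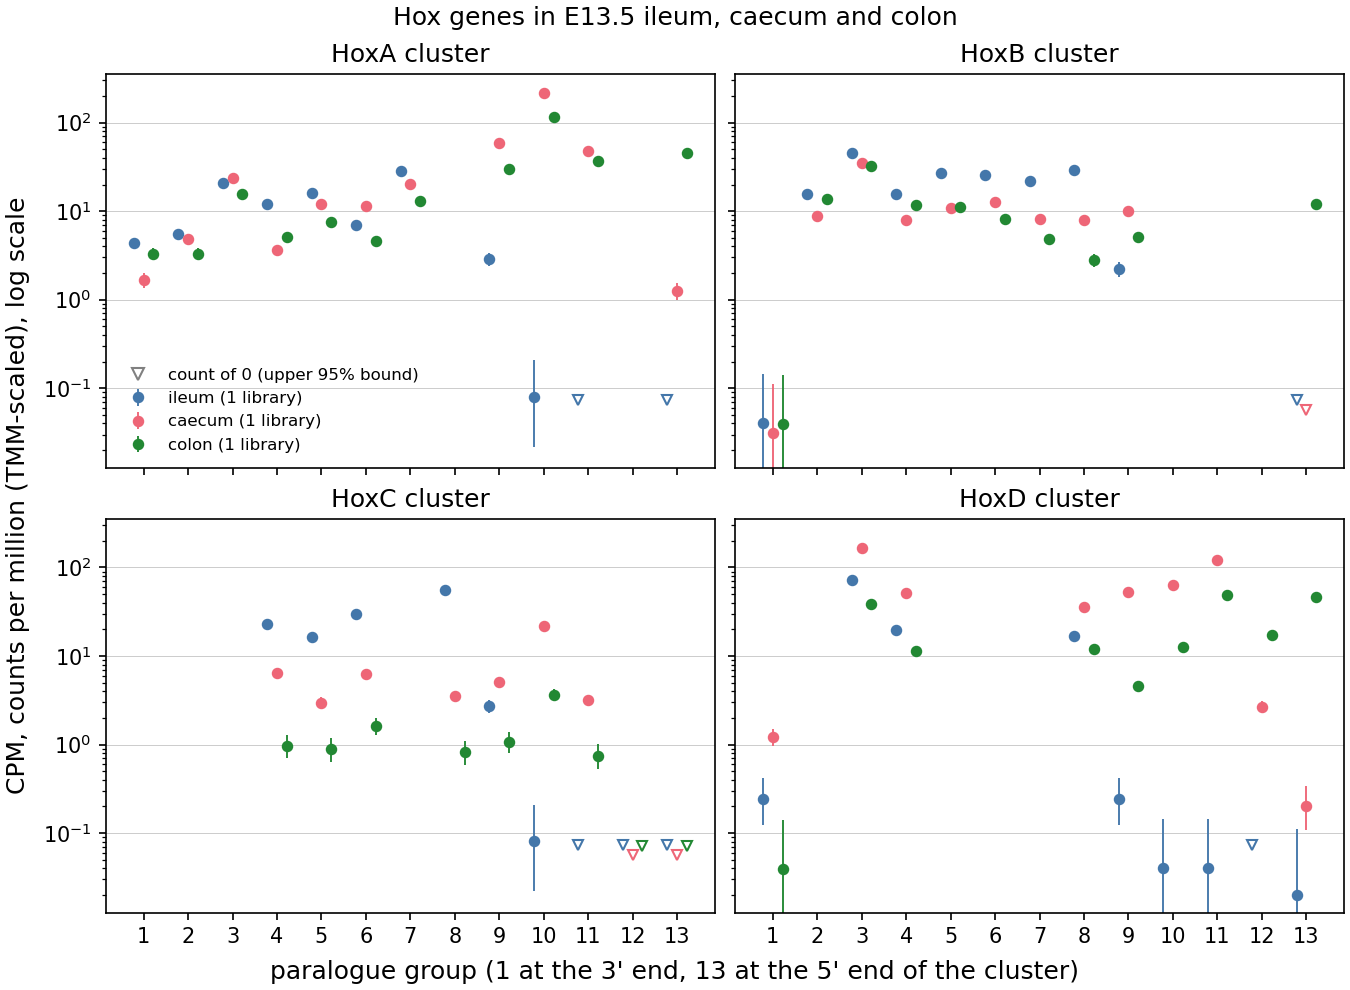
TMM-scaled CPM (log scale) of 39 Hox genes by paralogue group in the ileum, caecum and colon libraries, 1 library per tissue, with 95% Poisson intervals of the count and open triangles at the upper bound where the count was 0. Groups 10 to 13 are nearly absent from the ileum, HoxC genes of groups 4 to 8 are highest there, and Hoxa13, Hoxb13 and Hoxd13 are highest in the colon.

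Most of the genes that led the difference between the caecum and ileum libraries on the caecum side were Hox genes. Besides the Hox genes, Six2, a homeobox gene, Rxrg, a retinoid X receptor, and Gdf5, a ligand of the BMP family, were 159-fold (43.8 to 1318), 91.9-fold (54.6 to 169) and 89.6-fold (34.7 to 330) higher in the caecum. Gata4, a zinc finger factor of the proximal intestine, had 702, 4 and 58 counts and was 228-fold (88.8 to 840) higher in the ileum. Cps1, which encodes the entry enzyme of the urea cycle, was 29.8-fold (23.8 to 37.8) higher in the ileum, and Fabp2, a fatty acid binding protein of enterocytes, was 33.8-fold (12.8 to 126) higher. Sfrp1, a secreted WNT antagonist, and Grem1, a BMP antagonist, were 13.2-fold (12.3 to 14.2) and 10.4-fold (8.62 to 12.8) higher in the ileum. Among 17827 genes compared, 819 were at least 2-fold higher and 449 at least 2-fold lower in the caecum. Simulated counting noise gave 36.9 and 17.4 such genes.

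By the naming rule the caecum side of this comparison was led by Hoxa10, Hoxd11, Hoxa11, Hoxd10, Hoxa11as, Hoxd9, Hoxc10, Rxrg, Six2, Hoxc11, Hoxd12 and Gdf5. Hoxa11, with 0 counts in the ileum, was at least 789-fold higher in the caecum, and Hoxc11 and Hoxd12 were at least 52.3-fold and at least 43.8-fold higher. Hoxa11as, a transcript that overlaps Hoxa11 on the other strand, was 1497-fold (414 to 12365) higher, and reads of the pair were not told apart here. The ileum side was led by Gata4 and Cps1, followed by Cfi, a complement factor, at 29.7-fold (17.5 to 55.0), and H2-T3, a class I major histocompatibility gene, at 55.9-fold (15.0 to 469). Slc4a10, a bicarbonate transporter, and Cyp1b1, a cytochrome P450, were 15.2-fold (13.1 to 17.6) and 10.1-fold (8.90 to 11.6) higher in the ileum, and Hoxc8, Sh3bgr and Tm4sf20 were 16.0-fold, 11.2-fold and 12.1-fold higher. Gata4 lies at chromosome 14, 63817759 to 63890529, Cps1 at chromosome 1, 67169600 to 67277833, Six2 at chromosome 17, 86083608 to 86087594 and Gdf5 at chromosome 2, 155766759 to 155771103.

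Smooth muscle genes were lower in the caecum than in the ileum library, and Fgf10, Etv4 and Etv5 were higher. Actg2, Myh11 and Cnn1, which encode contractile proteins, were 3.12-fold (3.06 to 3.19), 3.03-fold (2.98 to 3.09) and 3.06-fold (2.90 to 3.23) higher in the ileum, and the smooth muscle list had 8 of 14 measured members at least 2-fold lower in the caecum and 0 higher. Myocd, Synpo2 and Synm stayed within 2-fold. Fgf10, a ligand made by mesenchyme, and Etv4 and Etv5, targets of FGF signalling, were 13.4-fold (11.2 to 16.2), 4.18-fold (3.67 to 4.77) and 3.47-fold (3.28 to 3.68) higher in the caecum. Pitx1, a paired-like homeobox gene, was 4.88-fold (4.33 to 5.52) higher in the caecum. Gdf10, of the BMP family, was 22.7-fold (19.8 to 26.1) higher, and Prrx1, Tnc and Twist1, which are genes of mesenchyme or its matrix, were 48.0-fold (20.3 to 149), 7.51-fold (6.73 to 8.41) and 3.10-fold (2.63 to 3.67) higher.

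Against the colon, the caecum side was led by Apob and the colon side by 5' Hox genes. Apob, an apolipoprotein of chylomicrons, was 63.7-fold (46.3 to 90.3) higher in the caecum, and Muc13, a membrane mucin, was 49.9-fold (30.6 to 87.7) higher. Cbln1, a secreted protein of the C1q family, was 102-fold (43.3 to 314) higher in the caecum. On the colon side stood Hoxb13, Hoxd13, Evx2 and Hoxa13, joined by Isl1 and Isl2, LIM homeobox genes, which were 44.8-fold (24.8 to 90.5) and 34.1-fold (23.7 to 50.9) higher in the colon. S100a14, an S100 calcium binding protein, was 158-fold (61.5 to 583) higher in the colon, and Sfrp1 was 23.7-fold (22.1 to 25.5) higher. Among 17900 genes compared, 914 were at least 2-fold higher and 490 at least 2-fold lower in the caecum, where noise alone gave 35.9 and 17.5. Without a count minimum the numbers were nearly even, at 2494 and 2328, while with a minimum of 100 counts they were 563 and 241. With intervals wholly beyond 2-fold they were 512 and 229.

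The named genes higher in the caecum than in the colon also included Gdf5 at 61.4-fold (28.0 to 168), Rbp4, a retinol carrier, at 20.8-fold (17.4 to 25), and Adamdec1, a disintegrin-like protease, at 27.5-fold (21.9 to 34.9). Rxfp2, a relaxin family receptor, Htr2a, a serotonin receptor, and Cck, the cholecystokinin gene, were 21.7-fold (14.4 to 34.5), 29.5-fold (11.3 to 110) and 29.3-fold (11.2 to 109) higher. Mpo, the myeloperoxidase gene, had 8, 118 and 0 counts and was at least 31.1-fold higher. Those higher in the colon included Oit1 with 0, 0 and 179 counts, Il1rn, an interleukin 1 receptor antagonist, at 68.3-fold (18.4 to 571), and Mc5r, a melanocortin receptor, at 101-fold (17.6 to 4044). Hoxb13 was at least 261-fold and Oit1 at least 75.4-fold higher in the colon than in the caecum. Apob lies at chromosome 12, 7984454 to 8023641, Hoxb13 at chromosome 11, 96055630 to 96058761 and S100a14 at chromosome 3, 90330778 to 90332755. Cbln1 appears under 2 overlapping identifiers with the same pattern. Both entered the numbers of genes, and the gene is described once here.

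The colon and ileum libraries, taken from the ends of the sampled gut, had the most genes 2-fold or more apart and the lowest correlation of the 3 pairs. Hoxa13, Hoxd13 and Hoxb13 were at least 748-fold, 2288-fold (410 to 90399) and at least 201-fold higher in the colon, and Six2 was 619-fold (171 to 5117) higher. Fgf10 was 28.7-fold (24.0 to 34.6) and Etv4 8.49-fold (7.50 to 9.65) higher in the colon than in the ileum. Lgr5, an R-spondin receptor found on intestinal stem cells, was 110-fold (55.6 to 256) higher in the ileum, as were Apob at 92.4-fold (67.2 to 131) and Muc13 at 97.6-fold (59.9 to 171). Tlx2, Fabp7 and Prph, genes of enteric neurons and glia, were 13.6-fold (10.7 to 17.6), 8.15-fold (6.66 to 10.1) and 5.41-fold (4.66 to 6.29) higher in the ileum. Of 17579 genes compared, 710 were at least 2-fold higher and 755 at least 2-fold lower in the colon, and noise alone gave 27.9 and 22.5. The correlation of log2 values across genes was 0.970, against 0.975 for caecum and ileum and 0.976 for caecum and colon, so the 3 were close. Another measure ranked the pairs otherwise. The mean squared difference over the counting variance was smallest for colon and ileum, at 46.2 against 67.5 for caecum and ileum and 52.3 for caecum and colon.

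The colon side of this pair was named as Hoxa11as, Hoxa13, Hoxa10, Hoxa11, Hoxd13, Hoxd11, Hoxd12, Six2, Hoxb13, Evx2, Hoxd10 and Oit1. Hoxa10 was 1427-fold (557 to 5238) higher in the colon, Hoxa11as 2255-fold (624 to 18627), Hoxd11 1205-fold (333 to 9952) and Hoxd10 316-fold (87.1 to 2614), while Hoxa11 was at least 611-fold, Hoxd12 at least 286-fold, Evx2 at least 124-fold and Oit1 at least 58.0-fold higher. On the ileum side Hoxc8, Adamdec1 and Cps1 were joined by Lgals2, a galectin, at 50.3-fold (34.2 to 77.4), Cyp1b1 at 42.0-fold (31.7 to 56.7) and Tnn, a tenascin of the matrix, at 25.1-fold (20.8 to 30.5). Adamdec1 was 55.5-fold (44.3 to 70.5) and Cps1 52.4-fold (37.7 to 75.1) higher in the ileum. Lect2, Prodh2 and H2-T3 had 0 counts in the colon and were at least 51.1-fold, at least 39.4-fold and at least 29.5-fold higher in the ileum. Lgr5 lies at chromosome 10, 114887367 to 115024836 and Hoxa13 at chromosome 6, 52207693 to 52210874. For 453 of the 710 genes higher in the colon the caecum value lay between those of ileum and colon, and for 484 of the 755 lower genes it did too. The caecum stood at least 2-fold above both for 34 and 24 of these genes, and at least 2-fold below both for 33 and 13.

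A set of genes stood apart in the caecum library from both of its neighbours. Cbln1 (ENSMUSG00000031654, chromosome 8, 89992761 to 89996508) had 7, 642 and 5 counts in the ileum, caecum and colon and was 70.5-fold (34.0 to 176) higher in the caecum than in the ileum. Rxfp2, Rxrg and Pkib, an inhibitor of protein kinase A, were 40.5-fold (23.0 to 78.8), 91.9-fold (54.6 to 169) and 24.4-fold (13.1 to 51.5) higher than in the ileum and 21.7-fold, 13.7-fold (11.1 to 16.9) and 13.2-fold (8.34 to 22.3) higher than in the colon. Gdf5, Hoxd9, Col19a1, a collagen chain, Tcfap2b, now named Tfap2b, and Accn1, an ion channel now named Asic2, completed the genes named as highest. Col19a1 had 4, 210 and 8 counts, Tcfap2b had 2, 84 and 2, while Accn1 had 26, 605 and 48. Sfrp1 and Grem1 led the genes lowest in the caecum, Sfrp1 with 8364, 824 and 15468 counts, Grem1 with 948, 118 and 1385, followed by Gata4, which was 18.3-fold (6.79 to 69.5) higher in the colon than in the caecum.

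The other genes lowest in the caecum were Rgs5, a gene of pericytes, at 4424, 899 and 3772 counts, Trim31, Cdx1, a caudal-type homeobox gene, Gpa33, an intestinal surface antigen, Erp27, and the retinaldehyde dehydrogenases Aldh1a1 and Aldh1a7. Cdx1 was 6.73-fold (4.64 to 10) higher in the ileum and 5.61-fold (3.85 to 8.40) higher in the colon than in the caecum. Aldh1a1 was 7.72-fold (7.37 to 8.09) and Gpa33 4.43-fold (3.82 to 5.16) higher in the ileum than in the caecum. Aldh1a7, a close paralogue of Aldh1a1, was 5.58-fold (5.04 to 6.19) higher in the ileum. Trim31 had 104, 18 and 98 counts, while Erp27 had 60, 4 and 32. Of 17722 genes compared, 332 were highest and 104 lowest in the caecum by at least 2-fold against both, where independent comparisons would give 42.2 and 7.45 and counting noise 4.45 and 2.15. For the ileum the numbers were 240 highest (19.5 and 3.15) and 320 lowest (21.3 and 6.85) of 17401, and for the colon 275 highest (19.9 and 3.05) and 397 lowest (29.7 and 4.25) of 17474. Both comparisons of a tissue share its library, so part of each excess can come from that shared library.

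Apart from the hedgehog list, each signalling list held genes within 2-fold beside others that stood far apart between segments. Here and below, list medians are log2 values for caecum over ileum, caecum over colon and colon over ileum, in that order, and percentiles refer to random lists of matched expression, as a description of these libraries. The caecal budding list had medians of 0.90, 0.37 and 0.36 at percentiles 100.0, 100.0 and 100.0, with Fgf10, Etv4, Etv5 and Pitx1 at least 2-fold higher in the caecum than in the ileum and Fgfr2, Spry2 and Bmp4 within 2-fold. Fgf10 and Etv4 were 2.14-fold (2.03 to 2.26) and 2.03-fold (1.91 to 2.17) higher in the colon than in the caecum. The FGF list had medians of 0.33, -0.20 and 0.51 at percentiles 100.0, 0.1 and 100.0, and 6 of its 15 members were at least 2-fold higher in the colon than in the ileum, among them Dusp6 at 2.18-fold (2.06 to 2.30). The WNT list had medians of -0.05, 0.77 and -0.36 at percentiles 20.1, 100.0 and 0.0. Of its members Rspo2 and Dkk1 were 8.03-fold (5.82 to 11.3) and 7.69-fold (3.08 to 24.7) higher in the caecum than in the ileum, Rspo3 and Fzd10 were 6.39-fold (5.61 to 7.30) and 6.86-fold (5.64 to 8.40) higher in the ileum than in the colon, and Tcf7, Wnt2b and Dkk2 stayed within 2-fold.

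The BMP and TGF-beta list had medians of 0.25, 0.19 and 0.26 at percentiles 99.9, 99.8 and 100.0, with Fst, a secreted antagonist, 4.38-fold (4.15 to 4.62) higher in the caecum than in the colon and Bmp3 11.9-fold (8.93 to 16.3) higher in the ileum than in the colon. Inhba, an activin chain, was 17.9-fold (10 to 35.2) higher in the colon than in the ileum, and Bmp5, Bmp7 and Id2 stayed within 2-fold. Of the 12 hedgehog genes, 12 were within 2-fold in both caecum comparisons, with medians of 0.04, -0.01 and 0.08, and only Shh reached 2-fold, at 2.05-fold (1.93 to 2.18) higher in the ileum than in the colon. The retinoic acid list had medians of -0.09, 0.02 and -0.50 at percentiles 13.8, 57.8 and 0.0. Its members split, since Crabp2, Cyp26a1 and Crabp1 were 11.5-fold (9.56 to 14), 9.87-fold (5.49 to 19.5) and 2.23-fold (1.95 to 2.57) higher in the caecum than in the ileum while Cyp26b1 was 3.16-fold (2.85 to 3.50) higher in the ileum, and Aldh1a2 and Rdh10 stayed within 2-fold. The regional transcription factors had medians of 0.03, 0.41 and -0.26. Gata5 was 8.27-fold (6.65 to 10.4) higher in the ileum than in the caecum, Nr2f1 was 2.15-fold (2.0 to 2.31) higher in the colon than in the caecum, and Cdx2, Gata6, Meis1 and Nr2f2 stayed within 2-fold.

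The gut epithelium list differed little between the segments, while 5 of 11 measured small intestinal absorptive genes were at least 2-fold lower in the colon than in the ileum and 0 higher. The gut epithelium list had medians of 0.05, -0.12 and 0.05, with Epcam, Cdh1, Cldn7 and Krt8 within 2-fold throughout. Foxa2, a forkhead factor, was 5.89-fold (4.55 to 7.73) higher in the colon than in the ileum, and Hnf4g and Elf3 were 2.54-fold (2.31 to 2.80) and 2.52-fold (2.23 to 2.86) higher in the ileum than in the caecum. The small intestinal absorptive list had medians of -0.29, 0.56 and -0.87 at percentiles 0.3, 99.8 and 0.0, with Cdhr2, Cdhr5 and Dpp4 at 4.60-fold (3.22 to 6.73), 3.01-fold (2.45 to 3.70) and 2.81-fold (2.66 to 2.96) higher in the ileum than in the colon and Mttp and Anpep within 2-fold. The colonic epithelial list, of which 5 to 7 members were measured, had medians of 0.89, 0.92 and 0.25, of which the first 2 fell to -0.02 and 0.04 with a minimum of 100 counts, with Tff3 3.29-fold (2.03 to 5.58) higher in the caecum than in the ileum, Krt20 3.80-fold (3.17 to 4.58) higher in the ileum than in the colon, and Fxyd4 13.3-fold (4.82 to 51.0) higher in the colon than in the caecum. The enteroendocrine list had medians of 0.11, 0.71 and -0.68, with Chgb 3.29-fold (2.60 to 4.22) higher in the caecum than in the colon, and with Neurog3 and Neurod1 at 0 counts in every library.

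Enteric nervous system genes were at similar levels in the ileum and caecum and lower in the colon. The list of 23 measured genes had medians of 0.10, 1.0 and -1.03 at percentiles 94.5, 100.0 and 0.0, and 13 of them were at least 2-fold lower in the colon than in the ileum and 0 higher. Th, Chrna3, Stmn3 and Elavl3, genes of neurons, were 14.7-fold (6.51 to 41.3), 3.14-fold (2.87 to 3.44), 3.17-fold (2.69 to 3.75) and 3.0-fold (2.58 to 3.49) higher in the ileum than in the colon. Ret, Erbb3 and Sox10, found in neural crest progenitors, stayed within 2-fold of the ileum. Interstitial cell of Cajal genes had medians of 0.15, -0.30 and 0.44, with Kit 3.13-fold (3.02 to 3.23) higher in the colon than in the ileum and Etv1 and Cd34 within 2-fold. The smooth muscle list had medians of -1.23, -0.36 and -0.63 at percentiles 0.0, 0.0 and 0.0.

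Mesenchyme genes had medians of 0.28, 0.28 and 0.11, with Lum, a matrix proteoglycan, 12-fold (11.1 to 12.9) higher in the ileum than in the colon, Postn 2.76-fold (2.71 to 2.82) higher in the caecum than in the ileum, and Pdgfra, Col3a1 and Foxf1a within 2-fold. The extracellular matrix list had medians of 0.06, 0.00 and 0.08, with Col9a1 4.77-fold (4.42 to 5.15) higher in the colon than in the ileum, Col14a1 2.50-fold (2.42 to 2.58) higher in the ileum than in the caecum, and Col4a1, Col4a2 and Lama1 within 2-fold. Mesothelial genes had medians of 0.18, -0.21 and 0.45, with Msln 16.1-fold (9.69 to 28.7) higher in the colon than in the caecum and Upk3b and Krt7 within 2-fold. Endothelial genes, with Pecam1, Cdh5 and Kdr within 2-fold, had medians of -0.09, -0.31 and 0.21, and Lyve1 was 2.32-fold (1.77 to 3.05) higher in the ileum than in the caecum. Leukocyte genes had medians of 0.12, 0.18 and 0.17, with Csf1r, Ptprc and Cx3cr1 within 2-fold and Lyz2 2.76-fold (2.29 to 3.34) higher in the colon than in the caecum.

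**Figure D3:**
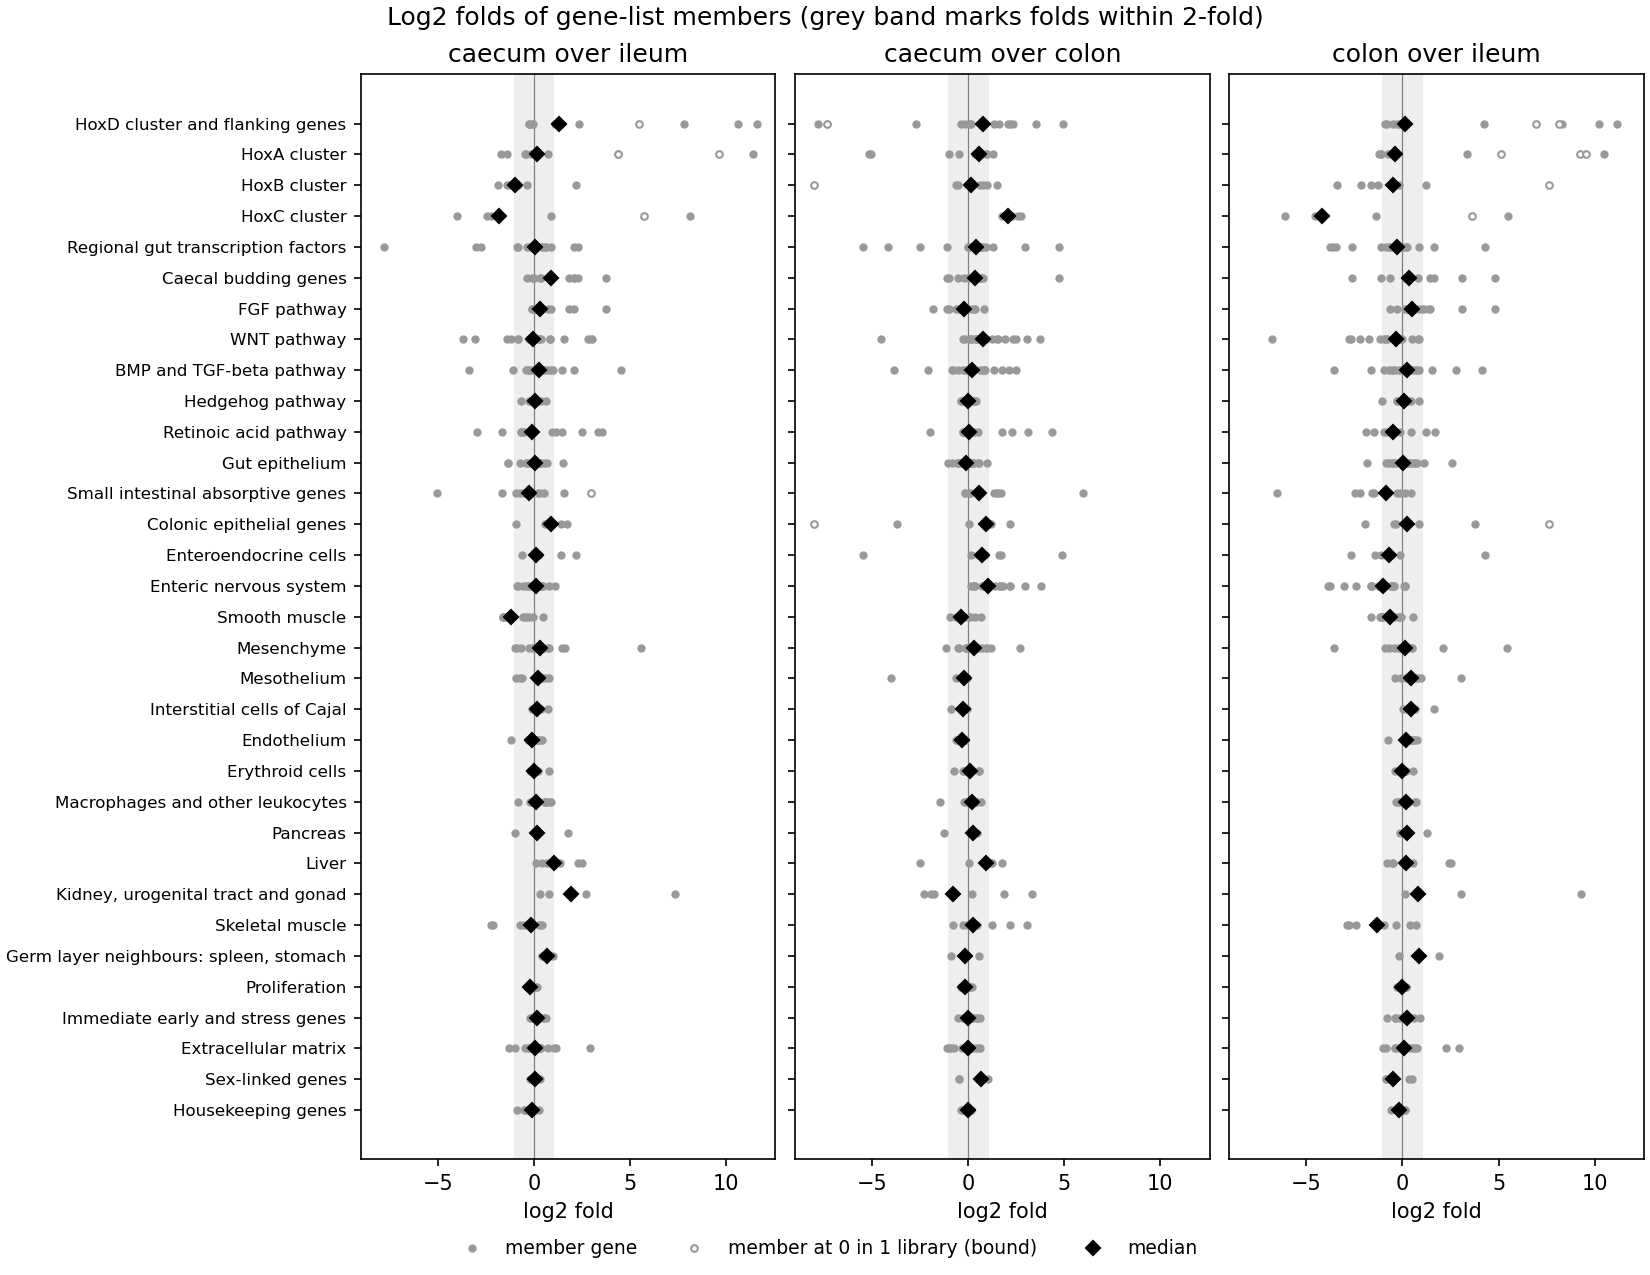
Log2 folds of the measured members of 33 gene lists (grey dots), with open dots for the bound of members at 0 counts in a library and black diamonds for list medians, in 3 panels for caecum over ileum, caecum over colon and colon over ileum, 1 library per tissue. The HoxC median lies farthest from 0 for caecum over colon and for colon over ileum, the kidney, urogenital and gonad median does for caecum over ileum, and most list medians lie in the grey band that marks folds within 2-fold.

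Lists of neighbouring organs were measured to read what the dissected segments held. The liver list had medians of 1.01, 0.93 and 0.21, with Afp, Ambp and Trf, which encode serum proteins, 5.58-fold (5.05 to 6.19), 4.94-fold (4.15 to 5.91) and 2.58-fold (2.44 to 2.74) higher in the caecum than in the ileum, and Alb at 6, 8 and 36 and Ahsg at 0, 0 and 0 counts. The pancreas list, with 3 measured members, had medians of 0.14, 0.25 and 0.24, of which 0.14 rose to 1.74 with a minimum of 100 counts, and Ptf1a, Ins2 and Prss1 had 0 counts in every library. The kidney, urogenital and gonad list had medians of 1.94, -0.79 and 0.80 over 5 or 6 members, of which -0.79 turned to 0.19 with a minimum of 100 counts, with Sall1 6.39-fold (5.38 to 7.63) higher in the caecum than in the ileum, Six2 as given above and Star within 2-fold. The skeletal muscle list had medians of -0.18, 0.23 and -1.35, of which -0.18 fell to -1.33 with a minimum of 100 counts, with Myl1 and Actc1 6.92-fold (3.65 to 14.5) and 5.37-fold (3.90 to 7.53) higher in the ileum than in the colon, Mylpf and Ttn within 2-fold and Myod1 at 2, 2 and 0 counts. The spleen and stomach list had only Sox2 and Tff1 measured, with medians of 0.68, -0.18 and 0.86, of which -0.18 turned to 0.57 and 0.86 to -0.18 with a minimum of 100 counts, Tff1 3.73-fold (2.38 to 6.05) higher in the colon than in the ileum and Nkx2-5 at 0 counts in every library.

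Measured cell division, stress and housekeeping genes stayed within 2-fold, though some of their list medians lay beyond nearly all random lists. Proliferation genes, among them Mki67, Top2a and Pcna, all stayed within 2-fold, with medians of -0.19, -0.18 and -0.03 at percentiles 0.1, 0.0 and 38.9. The list was thus slightly lower in the caecum than in both other libraries. Immediate early and stress genes, among them Fos, Jun and Hspa1a, also stayed within 2-fold, with medians of 0.14, -0.01 and 0.22 at percentiles 87.1, 44.2 and 98.4. So did housekeeping genes such as Actb, Gapdh and Hprt, with medians of -0.11, -0.02 and -0.16 at percentiles 8.8, 32.0 and 0.2. Erythroid genes had medians of -0.01, 0.11 and -0.01, with Hbb-y and Alas2 within 2-fold, and haemoglobin transcripts took 0.217%, 0.219% and 0.218% of counts in the ileum, caecum and colon. Sex-linked genes had medians of 0.06, 0.66 and -0.51, and each library held Xist and Y-linked transcripts, with Xist at 48888, 56279 and 63064 counts, Ddx3y at 1716, 1946 and 969, while Uty had 1169, 1712 and 670. Uty was 2.02-fold (1.85 to 2.21) higher in the caecum than in the colon. Xist was highest and Ddx3y and Uty were lowest in the colon library. The mix of female and male embryos may therefore differ between libraries, which cannot be told apart from tissue here. In total, 30 of the 99 list medians lay 0.5 log2 or more from 0.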

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

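All counts of genes stayed within 1.5 times under median-of-ratios, total-count and upper-quartile scaling, and the 2 alternatives added after seeing the data, the first and the second column alone, did the same. So did the counts for pairs of tissues under total counts without haemoglobin, mitochondrial and the 50 most abundant features. In that setting the highest and lowest counts, the folds of named genes and the list medians were not run. Stricter and looser thresholds moved the counts by construction. Values follow in the order caecum over ileum higher and lower, caecum over colon higher and lower, colon over ileum higher and lower, then highest and lowest in the ileum, caecum and colon. Without a count minimum they were 2787, 1854, 2494, 2328, 2669, 2300, 1061, 1345, 1287, 742, 1371 and 1083. With a minimum of 100 counts they were 439, 268, 563, 241, 336, 474, 156, 142, 196, 54, 134 and 229. With intervals wholly beyond 2-fold they were 397, 233, 512, 229, 347, 422, 130, 115, 157, 44, 131 and 200. At a fold of 4 they were 249, 101, 256, 129, 244, 229, 60, 82, 75, 18, 80 and 92, and 3 of the 9 Hoxd genes stayed highest in the caecum against both, while 6 did under the minimum of 100 counts and under the interval rule. Folds of named genes were run under median-of-ratios, total-count and upper-quartile scaling and single columns. Of these, 3302 of 3315 stayed within their intervals and the other 13, of Actb, Col3a1, Gapdh and Xist, moved by 0.05 log2 or less. Of 395 list medians 375 stayed and 20 moved, all under the minimum of 100 counts, which leaves fewer members. For caecum over ileum the HoxD list with its flanking genes went from 1.29 to 1.18, retinoic acid from -0.09 to -0.31, small intestinal absorptive from -0.29 to -0.51, colonic epithelial from 0.89 to -0.02, pancreas from 0.14 to 1.74, liver from 1.01 to 1.37 and skeletal muscle from -0.18 to -1.33. For caecum over colon the HoxD list went from 0.75 to 0.16, regional transcription factors from 0.41 to 0.57, WNT from 0.77 to 0.59, retinoic acid from 0.02 to 0.15, small intestinal absorptive from 0.56 to 0.96, colonic epithelial from 0.92 to 0.04, liver from 0.93 to 1.16, kidney, urogenital and gonad from -0.79 to 0.19, spleen and stomach from -0.18 to 0.57, and immediate early and stress genes from -0.01 to 0.24. For colon over ileum the small intestinal absorptive list went from -0.87 to -1.18, spleen and stomach from 0.86 to -0.18, and immediate early and stress genes from 0.22 to -0.06. The pseudocount alternative was not run because counts were present. No paired analysis was possible because each tissue had 1 sample and no labels join them.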

Other observations

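Genes outside the lists fixed in advance, chosen after values were seen, added further differences. The urea cycle genes Otc and Nags, and Oat, which encodes ornithine aminotransferase, followed Cps1. Otc had 164, 18 and 9 counts in the ileum, caecum and colon, Nags 25, 1 and 2, and Oat 7616, 4048 and 4467. Ass1 and Asl stayed within 2-fold. In that list 4 of 10 genes were at least 2-fold lower in the caecum than in the ileum, with a median of -0.63. Cps1, which prompted the list, is 1 of these 4 and enters the median. Abcc9 and Kcnj8, which encode subunits of a potassium channel of pericytes, followed Rgs5 and were 3.46-fold (3.32 to 3.60) and 3.46-fold (3.06 to 3.92) higher in the ileum than in the caecum, and 3.22-fold (3.09 to 3.35) and 2.95-fold (2.60 to 3.35) higher in the colon. Pdgfrb, Cspg4 and Notch3 stayed within 2-fold. The medians of the pericyte list, which includes Rgs5 itself, were -0.66, -0.65 and -0.21 for caecum over ileum, caecum over colon and colon over ileum.

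Some receptors and ligands of cell guidance differed between segments, while 13, 14 and 14 of the 18 genes of that list stayed within 2-fold for caecum over ileum, caecum over colon and colon over ileum. Epha5, an ephrin receptor, was 8.32-fold (6.57 to 10.7) higher in the caecum than in the ileum and 7.39-fold (5.93 to 9.31) higher than in the colon, and Slit3 and Robo1 were 2.52-fold (2.37 to 2.68) and 2.17-fold (2.10 to 2.25) higher than in the ileum. Epha7 was 2.44-fold (2.34 to 2.55) higher in the caecum than in the ileum, Epha3 was 3.36-fold (3.02 to 3.74) higher in the ileum, and Ntn1, the netrin gene, was 3.57-fold (3.29 to 3.88) higher in the ileum than in the colon. The guidance list had medians of 0.32, 0.05 and 0.26, and the lists added after values were seen were not placed among random lists. Gdnf, the ligand of the Ret receptor complex, was 2.15-fold (2.01 to 2.29) higher in the colon than in the ileum, Edn3 had 3350, 7644 and 4966 counts, and the list of GDNF and endothelin ligands had medians of 0.77, 0.16 and 0.53.

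The tests below for liver, epithelium, neural crest share, library size and urothelium were chosen only after the result was seen, and those for yolk sac, gene length and basal keratinocytes were written before theirs. The tissue itself, which is the design, stays open as an untested explanation of every pattern, and differences in the share of a cell type were the only biological explanations weighed.

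The serum-protein genes Afp, Ambp, Trf and Rbp4 were higher in the caecum than in the ileum, Afp with 433, 3144 and 2400 counts in the ileum, caecum and colon. Afp was thus higher in the colon than in the ileum too, so its contrast was not particular to the caecum. Of the 7 measured genes of the liver list, 3 were at least 2-fold higher in the caecum than in the colon and 1 was lower. The tests of this pattern compared the caecum and the ileum only. Liver tissue in the caecum sample was weighed with the summed counts of Alb, Ahsg, Fga, Fgb and Fgg, at 83 and 105 in the ileum and caecum. Their fold had an upper bound of 1.31, below the lower bound of 5.05 for Afp, which argues against liver as the source. These bounds cover counting error of 1 library per tissue, so liver is not excluded. This sum replaced an earlier test on Alb alone, which had few counts and gave an upper bound of 3.58. A larger share of epithelium was weighed with the gut epithelium list, whose median was 0.05 with 1 of 20 members at least 2-fold higher. The list as a whole thus did not rise with the serum-protein genes. That argues against a larger share of epithelium, within the same limit of 1 library per tissue. Yolk sac tissue was weighed with Apoa2, Amn, Cubn, Soat2 and Spink3, whose median was -0.16 with 4 of 5 upper bounds below the lower bound of Afp. That met the bar set in advance, but the bar was wrong, since Cubn with 1104, Spink3 with 370 and Amn with 84 counts in the ileum had a baseline that would hide a small share, while Apoa2, with 3 and 21 counts in the ileum and caecum, was 5.38-fold (1.61 to 28.2) higher in the caecum. Soat2, with 28 and 18 counts, went the other way and was 2.02-fold (1.08 to 3.88) higher in the ileum, so the members with few counts in the ileum disagree. Yolk sac tissue in the caecum sample therefore stays open, as does expression of these genes by caecal cells. The level of Afp in the colon was not weighed.

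Enteric nervous system genes were lower in the colon than in the ileum, with a list median of -1.03. A lower share of neural crest cells as the whole cause was weighed against Sox10, which was 1.41-fold (1.31 to 1.51) higher in the ileum, and 14 of 22 other members had an upper bound below its lower bound. With 1 library per tissue the spread between genes was set against counting error only, which excludes nothing, so a lower share stays open. The colon library was 1.03 times the size of that of the ileum. Folds were already scaled to library size, so this value is no test of the pattern. Gene length bias gave a difference of -0.02 between short and long genes against -1.03 for the list. Later differentiation of neurons in the colon, with Ret and Erbb3 within 2-fold and Tubb3 and Stmn2 2.36-fold (2.18 to 2.56) and 2.36-fold (2.20 to 2.54) higher in the ileum, may also contribute and was not tested.

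S100a14, Anxa8, the Sprr2a copies and Il1rn, genes of stratified or barrier epithelium, were higher in the colon than in both other libraries, with Anxa8 at 2, 12 and 206 counts. Stratified epithelium of the anal canal or urogenital sinus was weighed with basal keratinocyte genes, of which 1 of 4, Krt15, had a lower bound above 2-fold against both libraries, while Krt14 had 43, 64 and 94 counts and was 1.86-fold (1.34 to 2.59) higher in the colon than in the caecum and 2.12-fold (1.47 to 3.12) higher than in the ileum. That met the bar set in advance, but the bar was wrong, since Krt5 with 3 and Trp63 with 15 counts in the colon lay too near the floor to exclude anything. Stratified epithelium therefore stays open. Bladder or other urothelium was weighed with 3 uroplakin genes, of which 1, Upk1a at 103, 240 and 452 counts, was higher in the colon, while Upk2 and Upk3a had 3 and 2 counts there. Urothelium could therefore contribute and stays open too.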
